A study of Homo sapiens with 10 samples.

How the data were processed

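Expression was measured on 10 arrays of total RNA from MDS-L, an established human myelodysplastic cell line grown with interleukin 3 at 30 ng/mL and 10% serum, per the labels' protocols. Cells had been transduced with short hairpin RNA (shRNA) against SIRT1, shRNA against TET2 or control shRNA, and each knockdown had its own control group. Groups and replicate numbers were taken from the labels: 3 controls and 3 knockdown samples in the SIRT1 set, and 2 controls and 2 knockdown samples in the TET2 set. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

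Per the labels' protocols, 0.5 µg of total RNA was amplified and labelled with the red dye Cy5, and each array held 1 sample. The arrays were of a human long non-coding RNA design. Per the file headers, the spot intensity was extracted with Agilent Feature Extraction 10.7.3.1 in a 1-colour protocol for the red channel, and the processed signal is a background-subtracted intensity on a linear scale that was not normalized between arrays. The submitters' processing notes name R 3.4.0 and limma. The deposited value table holds a linear intensity per probe for 31741 probes, all with IDs that begin with PH_hs. From the values, each of its columns equalled a normexp-corrected median spot signal times 1 factor per array, with an SD of the log2 ratio of at most 0.00236, and the factor brought the median over all 55104 non-control probes to between 6.45 and 6.46 on the log2 scale. The column medians of the table, on its linear scale, ran from 163.6 to 188.7. Its scale was linear, no centring of probes was found, and its direction was that of the signal.

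The files do not pair probe IDs with genes, and the reference table holds no probe IDs, so 0 probes had a gene symbol here. The levels of SIRT1 and TET2 and the gene lists fixed beforehand were therefore not analysed, and the rule for named genes (the genes with the largest absolute log2 fold change among those with an adjusted p under 0.05 and no overlap between groups, limited to probes with 1 gene symbol) could name none. In its place, 1 probe that rose and 1 that fell in each knockdown are given by ID, taken by the same criteria on the measured fold change. Since folds against dim probes are bounds, that choice does not rank the changes. Probes are described by the start of their ID, PH_hs or PH_lnc, whose meaning the files do not state.

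The values tested were log2 of the processed signal minus the 75th percentile of each array over non-control probes, so every fold change is relative to that percentile. Control spots and the 12 spots that carried an outlier flag were left out, and 0 spots were saturated. A probe was tested when it was well above background on every array of at least 1 of the 4 groups, which kept 25031 probes, 17834 of them PH_hs and 7103 PH_lnc. Each probe had 1 spot. Linear models were fitted to all 10 arrays in 4 groups with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Figures were drawn with matplotlib 3.10.9. Where a probe was not well above background on any array of a group, its fold is a lower bound, written "at least". That bound sets the mean of the brighter group against the mean of, per array, the higher of the dim probe's value and the lowest value among probes well above background.

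The fit was tested on simulated data with 200 changed probes among 25031. For shSIRT1 against its controls, 92 of 100 changes of 1 on the log2 scale and 46 of 100 changes of 0.5 were recovered. For shTET2 against its controls the counts were 83 and 13 of 100. These rates hold for few changed probes and for noise drawn separately for each probe. In the measured shSIRT1 comparison 14287 probes were called, so its rates may differ. The number of arrays limits the precision, most of all in the TET2 set. The share of probes well above background was between 38.6% and 46.1% per array.

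The headers place the 3 SIRT1 controls and shSIRT1 replicate 1 on slide 1, and the other 6 arrays on slide 2. Slide was tried as a fixed and as a random block. Other alternatives set before the data were examined were normexp followed by quantile normalization (on the median spot signal, since the files used here give no mean), quantile normalization of the processed signal, the deposited value table, other filters on dim probes, only the arrays compared, another variance prior, a block for the replicate number, a 2-fold minimum, outlier spots kept and each array left out in turn. Chosen after the data were seen were cyclic loess, the 75th percentile of PH_hs or of PH_lnc probes alone, the TET2 controls as a second reference for shSIRT1, slide 2 alone and a covariate from the PGK1 control spots.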

Results

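The data are 10 single-colour arrays of MDS-L cells that carried shRNA against SIRT1, a NAD-dependent protein deacetylase, shRNA against TET2, an enzyme that oxidises methylated cytosine in DNA, or control shRNA. The series title links SIRT1 to TET2 function, and the comparisons ask which transcripts change when either is knocked down. The SIRT1 set had 3 control and 3 knockdown samples, and the TET2 set had 2 and 2. The levels of SIRT1 and TET2 themselves were not analysed here because the files do not pair probe IDs with genes, so the knockdowns were not checked.

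The arrays of the SIRT1 controls stood apart from those of every other group. On the first principal component, which held 54.3% of the variance of the tested probes, the SIRT1 controls lay between -54.8 and -36.1 and the other 7 arrays between 10.1 and 35.1. The second component, with 17.1%, placed the 3 shSIRT1 arrays between 24.1 and 25.9 and the other 7 between -20.5 and -2.99. shSIRT1 replicate 1, on the slide of the SIRT1 controls, lay with the shSIRT1 arrays of the other slide. The spread of signal was also wider in the SIRT1 controls, with an interquartile range of 3.20 ± 0.04 log2 units (SD, n = 3), against 2.84 ± 0.03 in shSIRT1 (n = 3), 2.87 ± 0.01 in the TET2 controls (n = 2) and 2.82 ± 0.05 in shTET2 (n = 2). Correlations between replicates of a group were between 0.990 and 0.996 across probes.

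**Figure D1:**
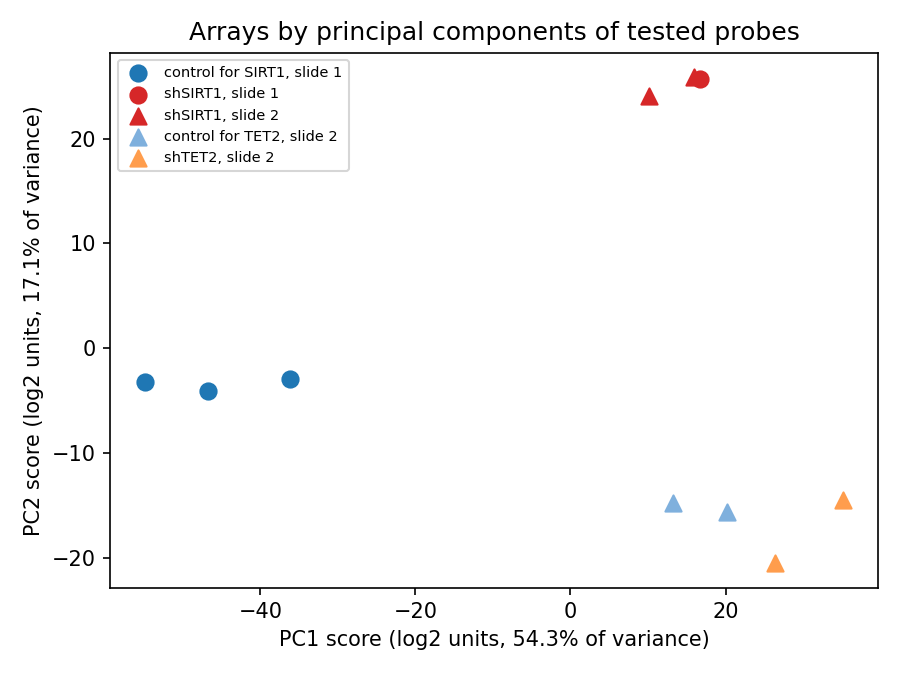
Scores of the 10 arrays on the first 2 principal components of the tested probes (log2 units), coloured by group, with circles for slide 1 and triangles for slide 2. The 3 SIRT1 control arrays lie between -54.8 and -36.1 on the first component, and the other 7 arrays between 10.1 and 35.1.

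Against their own controls, shSIRT1 cells differed at 14287 of 25031 probes, of which 7005 were higher and 7282 lower. Most changes were small: 91 of the higher and 184 of the lower probes changed at least 2-fold, and the median absolute log2 fold change of the called probes was 0.46. The probe groups moved apart. Of 7103 PH_lnc probes, 3902 were higher and 445 lower, with a median log2 fold change of 0.33 (quartiles 0.07 and 0.54), while of 17834 PH_hs probes 3085 were higher and 6801 lower, with a median of -0.18 (quartiles -0.37 and 0.12). The median of PH_lnc thus lay 0.51 log2 units above that of PH_hs, against an SD between arrays of 0.04.

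The split of calls in shSIRT1 into higher and lower depended on the scaling. A shift of all probes gains and loses calls, and the probes that turned under such a shift were not counted. Scaling to the 75th percentile of PH_hs probes moved the median over all probes from -0.06 to 0.13 and gave 4446 higher and 2852 lower PH_hs probes. Scaling to that of PH_lnc probes moved it to -0.43 and gave 1002 higher and 1955 lower PH_lnc probes, so the majority turned in each group. In the deposited value table, which lists PH_hs probes alone, 1272 were higher and 11837 lower, with a median of -0.43. Cyclic loess gave 5440 higher and 5471 lower probes, and 8421 of the 14287 probes were called the same way as before. The gap between the medians of PH_lnc and PH_hs, which no scaling by 1 factor per array can move, was 0.36 after quantile normalization and 0.34 after cyclic loess. Without a filter on dim probes it was 0.11.

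**Figure D2:**
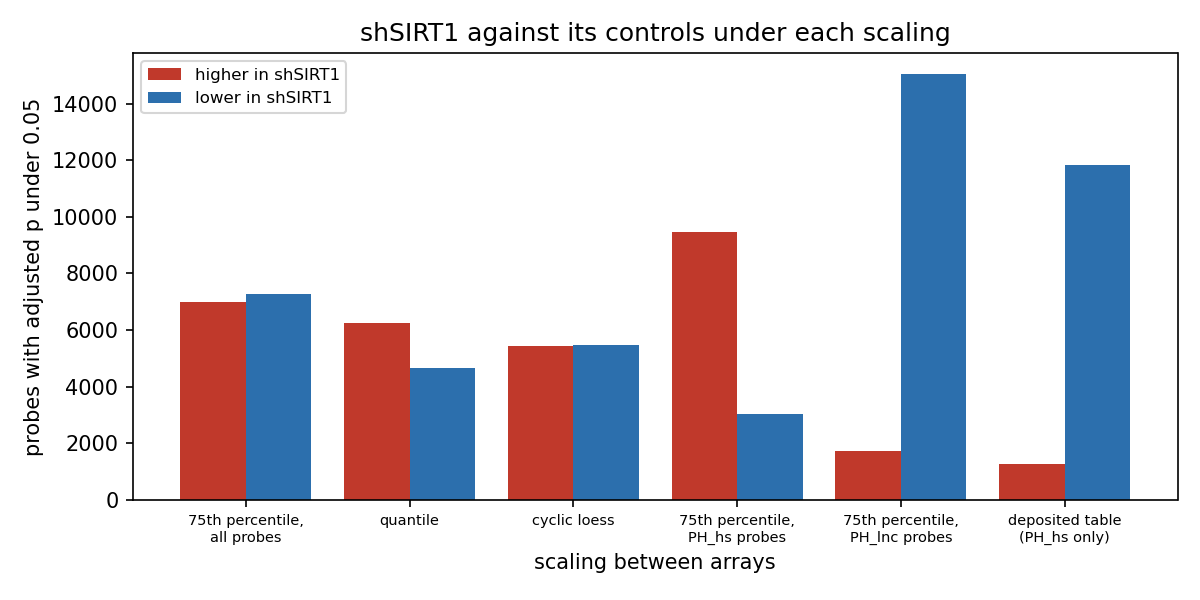
Number of probes with an adjusted p under 0.05 that were higher (red) or lower (blue) in shSIRT1 than in its controls, under several scalings between arrays and in the deposited table. With the 75th percentile of all probes 7005 were higher and 7282 lower. The deposited table, which lists PH_hs probes alone and also differs in background correction and spot signal, gave 1272 and 11837.

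The fold change in shSIRT1 also followed brightness. Among PH_hs probes the median went from 0.33 in the dimmest of 10 brightness bins to -0.32 in the brightest, and among PH_lnc probes from 0.52 to 0.00. In each bin PH_lnc lay above PH_hs, by 0.19 to 0.47. In shTET2 against its controls the same gaps were 0.00 to 0.04.

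**Figure D3:**
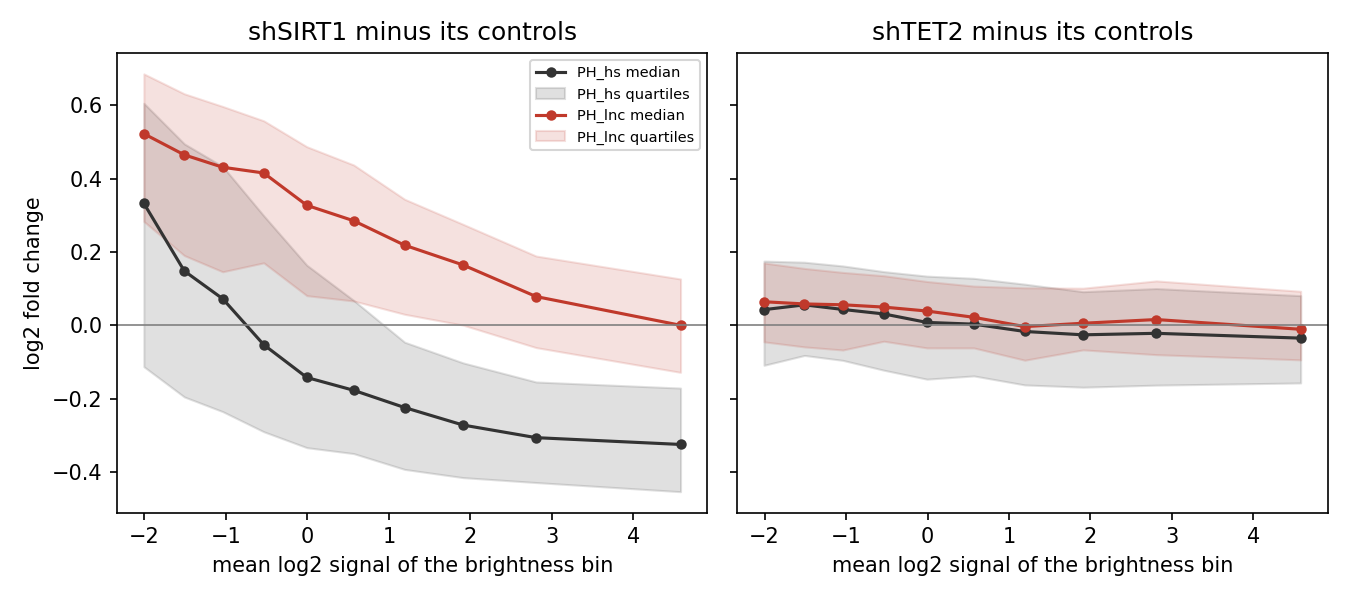
Median log2 fold change (points) and quartiles (bands) of PH_hs and PH_lnc probes in 10 bins of mean log2 signal, for shSIRT1 (left) and shTET2 (right) against their controls. PH_lnc lies above PH_hs by 0.19 to 0.47 in shSIRT1, and by 0.00 to 0.04 in shTET2.

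By ID, PH_hs_0012818 was at least 3.00-fold higher in shSIRT1 (limma adjusted p = 4.44e-05), with a measured mean of -0.21 ± 0.36 (SD, n = 3) against -2.08 ± 0.34 in controls, where it was not well above background on any array. PH_hs_0000003 was at least 4.43-fold lower (limma adjusted p = 2.45e-06), at -2.36 ± 0.31 against 0.22 ± 0.04 (n = 3 each), and was not well above background in any shSIRT1 array. Groups did not overlap at 60.2% of the tested probes, against 10% by chance for 3 against 3, an average over splits. Probes are not independent, so these shares do not test the difference. Well above background on every shSIRT1 array and on no control array were 418 probes, 234 of them PH_lnc, and 45 were so in controls alone, 2 of them PH_lnc. Detection also differed by slide, at 38.6% to 39.7% of probes on the arrays of slide 1, which hold the SIRT1 controls and shSIRT1 replicate 1 (38.6%), and 43.6% to 46.1% on those of slide 2. With slide as a block, 11619 probes were called. Only shSIRT1 lay on both slides, so that fit sets its replicate 1 alone against the SIRT1 controls. Keeping only that shSIRT1 array, assumed to vary like the other groups, is therefore not a separate check. The gap between the medians of PH_lnc and PH_hs was 0.56 either way.

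Set against the TET2 controls, the same shSIRT1 arrays differed at 1906 probes, 768 higher and 1138 lower, a reference chosen after the data were seen. The medians of PH_lnc and PH_hs were then close, at 0.03 and -0.00. Within brightness bins PH_lnc lay above PH_hs by 0.01 to 0.10. Called the same way against both control sets were 959 probes, 126 higher and 833 lower, while 234 were called in opposite directions. The split moved with the scaling, to 258 higher and 627 lower with the percentile of PH_hs and 26 and 1114 with that of PH_lnc. It was 22 and 1035 in the deposited table, which also differs in background correction, spot signal and probes. Independent lists would share 214.9 higher and 331.1 lower probes, but these lists share the shSIRT1 arrays and are not independent. Simulated comparisons with no change, which share those arrays too, gave 0 calls. An adjusted threshold gives about that by design. Neither figure therefore tells how many shared calls came from the shared arrays. Across probes, which are not independent replicates, the covariance of the fold changes was 0.0375, against 0.00863 simulated without change, and r was 0.309 against 0.450. Of the 959, 67 were at least 2-fold lower and 5 at least 2-fold higher against both sets. PH_hs_0000003 was at least 3.19-fold lower against the TET2 controls (limma adjusted p = 6.09e-06). It was not particular to shSIRT1: in shTET2 against the same controls its log2 fold change was -1.12 (limma adjusted p = 0.00327). Leaving out TET2 control replicate 1 or 2 gave 772 or 703 probes against the TET2 controls and 444 or 359 against both sets.

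In shTET2 against its controls, 618 probes passed the threshold, 150 higher and 468 lower. Falls also led among the larger changes, with 120 probes at least 2-fold lower and 25 at least 2-fold higher. PH_hs gave 131 higher and 410 lower probes, and PH_lnc 16 and 58. The medians of the groups were 0.00 and 0.04, and their gap of 0.04 was below the SD between arrays of 0.06. That gap was -0.01 without shTET2 replicate 1, 0.09 without shTET2 replicate 2 and 0.07 with no filter on dim probes. PH_hs_0009265 rose by 2.86 on the log2 scale (SE 0.20, limma adjusted p = 2.11e-05), and was above background on every array of both groups. PH_hs_0030879 was at least 2.49-fold lower (limma adjusted p = 2.11e-05), from -0.65 ± 0.01 to -3.59 ± 0.22 (SD, n = 2), and was not well above background in shTET2.

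The count in shTET2 rested on few arrays. Leaving out a TET2 control gave 212 (replicate 1) or 144 (replicate 2) probes, leaving out a shTET2 array gave 249 (replicate 1) or 186 (replicate 2), and leaving out SIRT1 control replicate 1, which enters through the pooled spread, gave 928. The arrays of slide 2 alone, which hold the whole TET2 set, gave 1678. Groups did not overlap at 52.8% of probes, against 33.3% by chance for 2 against 2, an average over splits. Probes are not independent, and an exact test of 2 against 2 can give no p under 0.333. The share is therefore no evidence of a difference beyond chance. The gap between the 5 and 3 control spots of PGK1, a glycolytic enzyme, was -2.85 ± 0.38 in shTET2 and -3.47 ± 0.40 in its controls (log2, SD, n = 2), and with that gap as a covariate 367 probes were called, 115 higher and 252 lower.

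The change in shSIRT1 differed from that in shTET2 at 6183 probes, 3114 with a more positive and 3069 with a more negative change in shSIRT1. Of 1812 such PH_lnc probes, 1670 were more positive, and of 4343 PH_hs probes 2909 were more negative. The split depended on the scaling, which gave 6062 more positive and 1473 more negative probes with the percentile of PH_hs and 457 and 8947 with that of PH_lnc. Among the 6183 were 5656 probes also called in shSIRT1 and 314 called in shTET2. PH_hs_0009265 moved in opposite directions: it was at least 2.70-fold lower in shSIRT1 (limma adjusted p = 1.81e-05), where it was not well above background on any array, and 2.86 log2 units higher in shTET2, and the difference passed the test (limma adjusted p = 6.45e-06). The fall of PH_hs_0009265 was seen against the SIRT1 controls alone: against the TET2 controls, its means were -2.38 ± 0.28 in shSIRT1 (SD, n = 3) and -2.04 ± 0.00 (n = 2), and it was not called (limma adjusted p = 0.315). The count was 3697 with slide as a block, where the shSIRT1 side rests on replicate 1 alone. It was 1786 without TET2 control replicate 1, 1921 without TET2 control replicate 2, 1120 without shTET2 replicate 2 and 3989 without shSIRT1 replicate 3.

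Called in the same direction in both knockdowns, each against its own controls, were 305 probes, 285 lower and 20 higher. Independent lists of these sizes would share 136.2 lower and 42.0 higher probes. The counts moved with the scaling while falls stayed the more frequent, at 177 lower and 32 higher with the percentile of PH_hs and 553 and 5 with that of PH_lnc. The deposited table, which also differs in background correction, spot signal and probes, gave 754 and 6. With the gap of the PGK1 control spots as a covariate, 172 probes were lower and 14 higher in both. The shSIRT1 side of these counts rests on the SIRT1 controls, which stood apart from every other group. Of the 305 probes, 149 were also called the same way in shSIRT1 against the TET2 controls, a reference that the shTET2 comparison shares. In opposite directions, 66 were lower in shSIRT1 and higher in shTET2, against 43.6 for independent lists. Another 13 were higher in shSIRT1 and lower in shTET2, against 131.0. Probes called in shTET2 in either direction were thus called lower in shSIRT1 more often than independent lists would give. Of the 468 probes lower in shTET2, 412 had a negative fold change in shSIRT1, as did 54.5% of all probes, while of the 150 probes higher in shTET2, 40 had a positive one. Among PH_lnc probes, 28 were lower in both, against 3.63 for independent lists, and 8 were higher in both, against 8.79. Across all probes, which are not independent replicates, r between the fold changes was 0.241 and rho 0.228. The comparisons share no array. The shared count fell to 118 or 79 without TET2 control replicate 1 or 2, and to 121 or 111 without shTET2 replicate 1 or 2.

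**Figure D4:**
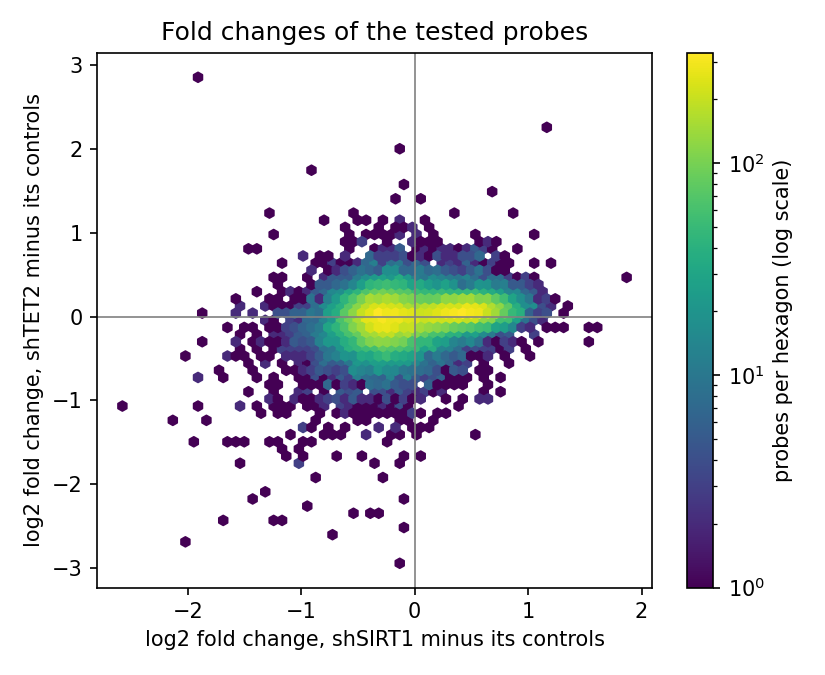
Log2 fold changes of the 25031 tested probes in shSIRT1 (horizontal) and shTET2 (vertical) against their own controls, with colour for the number of probes per hexagon on a log scale. Across probes r was 0.241.

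The control groups, which both carried control shRNA, differed from each other at 12199 probes, 6001 higher and 6198 lower in the SIRT1 controls. PH_lnc probes gave 3307 lower and 433 higher in the SIRT1 controls, and PH_hs probes 2869 lower and 5542 higher. The gap between the medians of PH_lnc and PH_hs was -0.44. The split of calls moved with the scaling, with 2667 higher and 8846 lower for the percentile of PH_hs and 13407 and 1699 for that of PH_lnc. Each control group lay on 1 slide, and with slide as a block, estimated through shSIRT1, 5297 probes were called. Without TET2 control replicate 1 or 2 the counts were 6652 and 8020.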

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

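All tests of explanations in this part were chosen after the results were seen, and the bound for the test of the knockdown on the PH_lnc gap was changed after its value was known. The difference between the effects of shSIRT1 and shTET2, tested as an interaction in limma, drew attention with 6183 probes. Signal was also seen in spots that entered no comparison: the ERCC-named control spots, read as a mean background-subtracted intensity over 12 names, gave at least 24.9 on each array of slide 2 and at most 17.4 on each array of slide 1. The 75th percentile of the arrays was higher on slide 2 as well, and as a percentage of it these spots gave 4.70% to 6.45% on slide 2 and 3.60% to 5.16% on slide 1, where shSIRT1 replicate 1 had the 5.16%, so the slides overlapped once scaled. The SIRT1 controls did not overlap the other arrays, at 3.60% to 4.13% against 4.70% to 6.45%. The cause of that was not tested.

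The first pattern is the call of over 1 in 2 probes in shSIRT1 against its controls; 5656 of the 6183 probes that differed between knockdowns were among these calls. A brightness-dependent trend was probably not the whole cause, since 10911 probes were called after cyclic loess, which is meant to remove such trends. Of the original calls, 58.9% were made again in the same direction. The trend left after cyclic loess is not given here. Slide was not the whole cause either: of the 12838 probes called from replicates 2 and 3 alone, 89.4% moved the same way between shSIRT1 replicate 1 and control replicate 1, which shared a slide and took no part in that choice. A candidate explanation is that the SIRT1 controls differed from every other group for a reason other than SIRT1, since 1906 probes were called between shSIRT1 and the TET2 controls and 12199 between the control groups. A baseline that differed between the sets together with a true effect of SIRT1 knockdown stays open. The 10 splits of the 6 arrays were too few for a share under 0.05. Of these, 1 split, the real one, gave as many as 14287 calls, and the highest of the others gave 0. Each other split mixes shSIRT1 and control arrays within a group, which widens the spread, so its count does not bear on the cause.

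The second pattern is the gap of 0.51 between PH_lnc and PH_hs probes in shSIRT1. Brightness was not the whole cause, since within brightness bins after quantile normalization the smallest gap was 0.19, above the SD between arrays of 0.04. Against the TET2 controls the gap was 0.034, and 0.01 to 0.10 within brightness bins, so most of the 0.51 may belong to the SIRT1 controls and not to the knockdown. That cannot be told apart here, because the TET2 controls belong to another set of samples and the sets can differ at baseline.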

How the results depend on the processing

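Cyclic loess, the percentiles of PH_hs or PH_lnc probes alone, slide 2 alone, the PGK1 covariate, and every result on the TET2 controls as a reference or on the gap between PH_lnc and PH_hs were chosen after the data were seen. The cause was not tested for any change below unless it is stated. In the order shSIRT1, shTET2, their difference, both knockdowns, the control groups, shSIRT1 against the TET2 controls and against both control sets, a 2-fold minimum left 275, 145, 409, 35, 403, 287 and 72 probes, fewer by construction. In shTET2 the count was 1001 in the deposited table, 248 with no filter, 1557 with only the arrays compared, 234 with the replicate block, 1678 on slide 2 alone, 367 with the PGK1 covariate, and 144 to 928 with 1 array left out. The difference gave 2895 with normexp and quantile normalization, 2854 with quantile normalization, 1306 with no filter, 1638 with the replicate block, 3697 with slide as a fixed block, 2462 with the shSIRT1 array of slide 1 alone, 3100 with cyclic loess, 9404 with the percentile of PH_lnc, and 1120 to 6584 with 1 array left out. Both knockdowns shared 760 in the deposited table, 114 with no filter, 562 with only the arrays compared, 117 with the replicate block, 558 with the percentile of PH_lnc, 186 with the PGK1 covariate, and 79 to 367 with 1 array left out. The control groups differed at 5297 with slide as a fixed block and 6652 to 12871 with 1 array left out. With no filter, 1122 probes were called against the TET2 controls and 498 against both sets, and with 1 array left out 703 to 2469 and 359 to 1146. The gap between PH_lnc and PH_hs in shSIRT1 was 0.30 with normexp and quantile normalization, 0.36 with quantile normalization, 0.11 with no filter, 0.46 with probes above background on all arrays, 0.56 with slide as a fixed block, 0.56 with the shSIRT1 array of slide 1 alone, 0.34 with cyclic loess, and 0.47 to 0.56 with 1 array left out. In shTET2 it was -0.01 to 0.09 with 1 array left out. Slide as a fixed block and the shSIRT1 array of slide 1 alone rest on the same shSIRT1 array and are not separate checks. The shSIRT1 count stayed within 1.5 times of 14287 under every setting run except the 2-fold minimum, from 10679 to 16766, but its share of higher calls, 49.0%, was 9.70% in the deposited table, 64.8% with no filter, 37.7% with probes above background on all arrays, 75.8% with the percentile of PH_hs and 10.3% with that of PH_lnc. The 7 calls of probes given by ID kept direction in all 173 fits of a call under an alternative. PH_hs_0009265 in shSIRT1 was, however, not called once the TET2 controls took the place of the SIRT1 controls (limma adjusted p = 0.315). These probes were chosen for their large changes, and leaving out arrays of the other set does not move their folds. Each was dim in some group, so the filter for probes above background on all arrays has no fit for them. Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.35, -0.40 and -0.27 in the SIRT1 set and -0.10 in the TET2 set, and the replicate block gave 11651 probes in shSIRT1. Not run were the mean of all probes of a gene, the levels of SIRT1 and TET2 and the gene lists, which need gene names, and the replicate block for the comparisons across sets (the control groups, and shSIRT1 against the TET2 controls or both control sets), which the block absorbs. The difference between knockdowns uses all arrays, so it has no value for only the arrays compared. Signal over background limits dim probes, since 45.4% of probes were tested.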

Other observations

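The tests in this part were chosen after the results were seen. Within groups, 1 axis held 39.6% of the variance between replicates. It followed the gap between the 5 and 3 control spots of PGK1 over the 10 arrays, both as deviations from the group means, with r = 0.826 and rho = 0.855 (exact permutation p = 0.00694 within groups, the smallest that 144 arrangements can give, and the same after Benjamini-Hochberg adjustment over 2 relations). The sign of the axis is arbitrary. Without the 2 arrays farthest from the median, r was 0.640. For the spots of GAPDH, another glycolytic enzyme, r was 0.655 and rho 0.685 (exact permutation p = 0.00694), and r was 0.580 without the 2 farthest. The hypothesis tested by this correlation is that replicates differed in the balance between the 5 and 3 ends of transcripts. The files do not explain the suffixes 5 and 3, and RNA integrity per sample was not analysed here, so what would set such a balance was not tested.

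The third pattern weighed is whether this balance bears on the calls in shTET2. The slope of each probe on the PGK1 gap was taken from the 6 arrays of the SIRT1 set, which hold no TET2 sample. In shSIRT1 that gap went with slide, at -2.86 on slide 1 (replicate 1) and -3.79 and -3.52 on slide 2 (replicates 2 and 3). The slopes may therefore carry a difference between slides as well. The PGK1 gap was -3.11 and -2.58 on the shTET2 arrays, and -3.19 and -3.75 on the TET2 controls. For GAPDH the groups overlapped, at -1.26 and -0.93 against -1.17 and -1.49. That the balance differed between shTET2 and its controls thus rests on PGK1 and few arrays. Of the 468 probes lower in shTET2, 79.5% had a slope of the matching sign, against 52.4% of all probes, and between 72.9% and 86.1% when each of the 6 arrays was left out, so this balance may account for part of these falls. Of the 150 higher probes, 42.7% matched, against 47.6% of all probes, so this measure showed no excess for the rises. Across probes, which are not independent replicates, r between the slopes and the fold changes in shTET2 was 0.387. The share alone therefore does not settle whether this balance bears on the rises. With the gap as a covariate, 226 of the 468 falls and 91 of the 150 rises were called again. The other 242 falls kept their sign. Their median log2 fold change went from -0.66 (quartiles -0.79 and -0.57) to -0.53 (-0.63 and -0.47) with a median SE of 0.14 before and after. The other 59 rises kept their sign too, with a median of 0.60 before and 0.52 after and a median SE of 0.13 and 0.14. Calls were lost in both directions, so their loss does not single out this balance. What ended these calls was not tested. An effect of TET2 knockdown on the falls stays open.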
